A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

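RNA was measured in diploid Saccharomyces cerevisiae cells of the SK1 background, a strain that sporulates rapidly and with high synchrony. Per the labels, the 4 strains were wild type, mre11delta, rad50delta and spo11Y135F. Each strain was measured at 0 h and at 4 h after transfer into sporulation medium, with 1 array per strain and time and 8 arrays in total. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads and 3 microg of it was labelled with biotin for Affymetrix YG-S98 arrays, which carry a single colour. The labels' protocols give Trizol as the extraction method of 3 arrays, which are wild type at 0 h and both arrays labelled mre11delta. The other 5 arrays were extracted with glass beads and RNeasy columns, which are wild type at 4 h and both arrays of rad50delta and spo11Y135F.

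The deposited values are signal intensities on a linear scale that the authors computed with MAS5, per the file headers and the submitters' processing notes. The scaling of the arrays to each other and the version of MAS5 are not given in the sources used here. The trimmed mean of the signal ran from 296 to 557 over the 8 arrays, a 1.88-fold range, while the mean of the bacterial spike controls varied 1.12-fold. The median signal ran from 97.3 to 196 over the arrays, and 92.1% to 96.4% of genes lay above the floor of 21 defined below. For these arrays, the number of arrays limits the precision.

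The array holds 9335 probe sets, of which 6504 carry 1 gene, 328 carry several genes and 2503 carry no gene name in the platform annotation, 60 controls among the last. All 6504 were matched to the reference annotation by gene identifier, and genes are named here by symbol and locus tag, which gives chromosome and arm. For each of 5656 genes 1 probe set was kept, a gene-specific type before a shared type and then the set with the highest mean. A shared probe set was the only set of 206 genes, 187 of them tested, and values of such genes are uncertain because related genes can add to them. Among 283 genes with at least 2 probe sets above the floor, the change over time had opposite signs between probe sets in 72, and in 0 of the 53 called genes among them. Values were used as deposited, with no further scaling, as log2 of the signal plus a pseudocount of 7, the 10th percentile of all values. Genes with a mean signal of at least 21, which is 3 times the pseudocount, were tested, 5475 in all.

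The only replicated comparison was 0 h against 4 h, with the 4 strains as replicates. It was fitted with limma 3.58.1 in R 4.3.3 with strain as block (3 residual degrees of freedom), a mean-variance trend in eBayes, a two-sided test and Benjamini-Hochberg adjustment over all genes at 0.05. The SE given beside a change is limma's moderated standard error. Of 28 gene lists fixed beforehand, the 27 with at least 5 tested members were tested with camera at its preset correlation, with camera's estimated correlation and with fry beside it. The mitochondrially encoded genes fell short of that number and were not tested. A relative median is the median change or difference of a list minus that of all tested genes.

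Strains were compared without a test, since each has 1 array per time. A gene was counted as standing apart where its value in a strain lay at least 2-fold above the highest or below the lowest of the other 3 strains at the same time and its highest value was at least 21. The same rule was applied to the change from 0 h to 4 h within each strain. With a strain left out, the range of the others can only narrow, so that a gap stays or grows by the rule itself. For each list, the median difference of a strain from the mean of the other 3, and of a mutant from wild type, is given with its percentile among 10000 random lists of the same size drawn from 10 bins of expression. These percentiles describe the arrays and are not p-values for a strain.

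The lists, the main tests and all alternatives except 1 were fixed before the data were examined, while most tests of flagged results were chosen after. The rule for naming genes was also written beforehand. It takes the 12 largest rises and the 10 largest falls over time that passed the test in the same direction in all 4 strains, and up to 4 members per list with the largest change past the threshold. For genes standing apart it takes the 12 largest gaps on each side for mre11delta at 4 h, 5 on each side for every other strain at 4 h, and 3 on each side at 0 h and for the change. To these it adds the mutated genes and the strain markers. Genes whose only probe set is shared were skipped except in the lists. The text prints a part of the genes that the rule takes.

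The scripts were tested on simulated data. Of planted 2-fold changes over time the limma fit called 0 of 67, of planted changes of 2 in log2 it called 7 of 67, and of planted changes of 4 in log2 it called 49 of 66. It called 1 of 5275 unchanged genes, and 0 genes where no gene was changed. In the simulation smaller changes than these were therefore mostly missed. It changed far fewer genes than the 802 called in the arrays, which makes the adjustment stricter, so it can understate what the fit calls. Alternatives were other scalings (median centring, quantile), pseudocounts of 1 and 28, other filters, the mean of a gene's probe sets, shared probe sets left out, no block, no trend, extraction method as a covariate, each strain left out, a 3-fold rule and comparisons within an extraction method. A fit within the RNeasy pairs alone was added after seeing the data. It rests on rad50delta and spo11Y135F only, and leaves fewer residual degrees of freedom than the main fit. Figures were drawn with matplotlib 3.10.9.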

Results

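The arrays compare yeast cells that the labels place at 0 h and at 4 h of meiosis, counted in sporulation medium. The strains are wild type and 3 mutants of the formation of meiotic DNA breaks. Mre11 and Rad50 are subunits of a complex that is needed to make and to process these breaks. Spo11 is the enzyme that cuts the DNA, and Y135F replaces its catalytic tyrosine. There are no replicate arrays within a strain and time, so values of single strains carry no error.

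The mutated genes were read first as a check of the labels. RAD50 (YNL250W) had a signal of 0.6 at 0 h and 3.4 at 4 h in rad50delta, and between 88.4 and 758 in the other 6 arrays. MRE11 (YMR224C) had a signal of 84.0 at 0 h and 108 at 4 h in the arrays labelled mre11delta, inside the range of 45.0 to 192 in the other 6 arrays. The MRE11 probes do not separate the arrays labelled mre11delta from the rest, and whether the probes lie within the deleted part is not given in the sources used here. Every direction given below for mre11delta rests on the label alone. SPO11 (YHL022C) carries a point mutation in spo11Y135F, so its signal of 1.7 at 0 h and 94.2 at 4 h there checks nothing. URA3 (YEL021W), a uracil synthesis gene used as a strain marker, read 496 at 0 h and 14.8 at 4 h in the arrays labelled wild type. In rad50delta it read 4.4 and 2.5, in spo11Y135F 357 and 91.3, and in the arrays labelled mre11delta 486 and 273.

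From 0 h to 4 h, 802 of 5475 genes changed, 582 of them higher and 220 lower at 4 h. Among genes above the floor of 21 in all 8 arrays, the largest rise was that of RNP1 (YLL046C), an RNA-binding protein, by 64.0-fold (adjusted p = 2.00e-07). The largest fall among them was that of PRY2 (YKR013W), a secreted sterol-binding protein, with a log2 change of -5.24 ± 0.62 (SE, n = 4 strains), a 37.7-fold decrease (adjusted p = 3.85e-06). Of the 582 genes that rose, 175 had a signal below the floor at 0 h in at least 1 strain, so that the size and order of their changes depend on the pseudocount. Of the 64 named genes that rose this held in all 4 strains for 16 and in at least 1 strain for 31. ECM11 (YDR446W), a component of the synaptonemal complex, read 2.1 to 14.8 at 0 h and rose by 7.91 ± 0.56 (adjusted p = 6.34e-09), a value that ran from 6.71 to 8.69 over the alternatives. Also from below the floor in at least 1 strain, MEI5 (YPL121C), an accessory protein of meiotic strand exchange, rose by 7.01 ± 0.49, and SPO16 (YHR153C), a synapsis initiation protein, by 6.78 ± 0.52. CDA1 (YLR307W), a chitin deacetylase of the spore wall, rose by 6.70 ± 0.62, and REC8 (YPR007C), the meiotic cohesin subunit, by 6.26 ± 0.57. Among the falls, ALD6 (YPL061W), the cytosolic aldehyde dehydrogenase that makes acetate, changed by -5.45 ± 0.61 (adjusted p = 1.85e-06), SAM4 (YPL273W), a methionine synthesis enzyme, by -4.09 ± 0.59, and the glucose kinase HXK2 (YGL253W) by -3.81 ± 0.64.

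Of the 802 genes, 743 changed in the same direction in all 4 strains and 799 changed at least 2-fold. The balance of rises and falls depended on the scaling. With median centring 969 genes changed, 409 higher and 560 lower, and with quantile normalization 817, 439 higher and 378 lower. The median log2 change over all genes was 0.19 as deposited and -0.22 with median centring. Wild type was also the only strain whose extraction method differed between the times. Without wild type 364 genes changed, 328 higher and 36 lower, and with extraction method as a covariate 382 changed, 346 higher and 36 lower. The covariate varies within a strain only in wild type, so it takes up the whole change of wild type. Both settings therefore estimate the time effect from the mutants alone, here and below, and are not separate checks. Within the RNeasy pairs of rad50delta and spo11Y135F alone, a fit chosen after seeing the data, 1214 genes changed and 355 of them were lower. With so few arrays that fit leaves fewer residual degrees of freedom than the main fit, so its larger count is not stronger evidence.

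Camera called all 6 lists of meiotic genes higher at 4 h with its preset correlation, and 0 of them with an estimated correlation. As deposited 0 of their members fell, and 1 fell with median centring or quantile normalization, in the middle list. Of the chromosome axis and synaptonemal complex genes 15 of 15 rose, and 15 adjusted over the list alone, with SPO13 (YHR014W), a regulator of meiotic chromosome segregation, at 6.03 ± 0.55 beside ECM11, SPO16 and REC8. Of the middle meiotic genes, the targets of the transcription factor Ndt80, 33 of 38 rose, 36 adjusted over the list alone and 21 with either other scaling, among them the spore membrane gene ADY3 (YDL239C) at 5.15 ± 0.56 and the phosphatase subunit GIP1 (YBR045C) at 5.05 ± 0.63. Of the spore wall and late sporulation genes 20 of 26 rose, 23 adjusted over the list alone and 16 with either other scaling, with LDS2 (YOL047C), a lipid droplet protein of sporulation, at 6.53 ± 0.60 and LDS1 (YAL018C) at 6.09 ± 0.62. Among genes of meiotic strand exchange and crossover 12 of 18 rose, and 13 adjusted over the list alone, with HOP2 (YGL033W) and the mismatch repair relative MLH3 (YPL164C) both at 5.38. Among genes of double-strand break formation 6 of 10 rose, and 8 adjusted over the list alone, with REC102 (YLR329W) at 6.29 ± 0.51, SPO11 at 4.99 ± 0.52 and REC114 (YMR133W) at 4.79 ± 0.51. Of the meiotic entry regulators 7 of 10 rose, and 7 adjusted over the list alone, with SLZ1 (YNL196C) at 6.58 ± 0.76 and the kinase IME2 (YJL106W) at 5.48 ± 0.57. By camera, the adjusted p was 2.89e-24 for the axis list, 3.21e-23 for the middle list, 7.47e-20 for the spore list, 2.51e-13 for strand exchange, 4.82e-08 for break formation and 3.82e-07 for entry, and for each of the 6 lists the adjusted p = 0.453 with an estimated correlation. Without wild type 5 of the entry genes, 5 of break formation, 14 of the axis, 10 of strand exchange, 23 of the middle and 15 of the spore genes rose. Relative to the median gene, the median change of the lists ran from 2.24 for entry to 4.96 for the axis.

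Of 81 cytosolic ribosomal protein genes 45 fell and 0 rose, 65 fell adjusted over the list alone, and 64 fell with median centring and 51 with quantile normalization. Without wild type, and likewise with extraction method as a covariate, only 8 of them fell, and within the RNeasy pairs 13 fell and 2 rose. RPS7A (YOR096W) changed by -2.95 ± 0.48 and RPS22A (YJL190C) by -2.80 ± 0.53, both proteins of the small subunit. The relative median of the list was -1.62 (camera adjusted p = 6.78e-30, and adjusted p = 0.631 with an estimated correlation), and 28 of its members have only a shared probe set and are uncertain. In the glycolysis and fermentation list 6 of 24 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone, with HXK2 the largest fall. With median centring 12 fell and with quantile normalization 2, while camera called the list lower (camera adjusted p = 5.14e-05, and adjusted p = 0.663 with an estimated correlation). In the amino acid biosynthesis list, targets of the activator Gcn4, 4 of 49 fell and 1 rose, and 2 fell and 1 rose adjusted over the list alone. With median centring 13 fell and 0 rose, and with quantile normalization 9 and 0. The asparagine synthetase ASN2 (YGR124W) changed by -1.90 ± 0.52, a call that is lost without wild type (adjusted p = 0.107). The relative median of that list was -0.90 (camera adjusted p = 0.000164, and adjusted p = 0.780 with an estimated correlation). In the mitotic G2/M cluster, a marker of cells still dividing, 2 of 15 fell, and 3 fell and 1 rose adjusted over the list alone, and 4 fell with median centring and 3 with quantile normalization. The camera adjusted p was 0.00628, and the adjusted p = 0.663 with an estimated correlation, and the call was lost within the RNeasy pairs (adjusted p = 0.292). Without wild type 1 glycolysis gene, 0 amino acid genes and 0 G2/M genes fell. Within the RNeasy pairs 8 glycolysis genes fell and 2 rose, 7 amino acid genes fell and 2 rose, and 4 G2/M genes fell and 3 rose. The G2/M septum synthase CHS2 (YBR038W) changed by -2.16 ± 0.57, a call lost without wild type (adjusted p = 0.116).

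The ribosome biogenesis list was called lower by camera (relative median -0.68, adjusted p = 0.00194, and adjusted p = 0.780 with an estimated correlation), while 0 of its 48 members passed the test and 0 passed adjusted over the list alone, and 3 fell with median centring. The call was lost without wild type (adjusted p = 0.174), without the arrays labelled mre11delta (adjusted p = 0.167), with extraction method as a covariate (adjusted p = 0.180) and within the RNeasy pairs (adjusted p = 0.340). Within wild type and the arrays labelled mre11delta the relative median of this list was -1.91 and -1.61, and within rad50delta and spo11Y135F it was 0.04 and 0.54.

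In the autophagy list, whose genes recycle cell contents in starvation, 6 of 22 rose, and 7 adjusted over the list alone, with the kinase ATG1 (YGL180W) at 3.93 ± 0.56 and the activating enzyme ATG7 (YHR171W) at 2.75 ± 0.57. Camera called the list higher (adjusted p = 0.000444), and the adjusted p = 0.663 with an estimated correlation, and the call was lost within the RNeasy pairs (adjusted p = 0.271). Without wild type 3 autophagy genes rose, as they did without rad50delta, while 8 rose without spo11Y135F and 8 within the RNeasy pairs. In the premeiotic S phase and DNA replication list 6 of 29 rose, and 9 adjusted over the list alone, and with either other scaling 2 fell, with the cohesin subunits SMC3 (YJL074C) at 3.15 ± 0.56 and SMC1 (YFL008W) at 2.39 ± 0.54. Its camera call (adjusted p = 0.0457, and adjusted p = 0.780 with an estimated correlation) was lost in 5 of 16 alternatives, which were without the arrays labelled mre11delta (adjusted p = 0.204), without rad50delta (adjusted p = 0.0940), without shared probe sets (adjusted p = 0.0598), with the floor of 70 (adjusted p = 0.0877) and within the RNeasy pairs (adjusted p = 0.420). Its rises numbered 3 without wild type, 2 without the arrays labelled mre11delta, 2 without rad50delta and 7 without spo11Y135F. Within the RNeasy pairs 9 of its genes rose and 2 fell. Of the haploid and mating-type specific genes, which mark cells that are not a/alpha diploids, 6 of 22 rose, 7 adjusted over the list alone and 4 with either other scaling. The a-factor receptor STE3 (YKL178C), at 2.15 ± 0.50, and the bud site and protease gene AXL1 (YPR122W), at 2.68 ± 0.51, were among them, and MFA1 (YDR461W), at 3.97 ± 0.55, has only a shared probe set and is uncertain. The camera adjusted p of the haploid list was 0.00985, and the adjusted p = 0.663 with an estimated correlation, and the call was lost within the RNeasy pairs (adjusted p = 0.0673). Without spo11Y135F 3 of its genes rose, and within the RNeasy pairs 8 rose and 1 fell.

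Among nitrogen catabolite repressed genes, which are used on poor nitrogen sources, 8 of 25 rose, and 8 rose and 1 fell adjusted over the list alone, with the regulator DAL80 (YKR034W) at 3.56 ± 0.56. With median centring 2 rose and 1 fell, and with quantile normalization 3 and 1. Without wild type 3 rose, without the arrays labelled mre11delta 4, without spo11Y135F 11, and within the RNeasy pairs 3 rose and 3 fell. The camera call of the nitrogen list (adjusted p = 0.0479, and adjusted p = 0.780 with an estimated correlation) was kept in only 5 of 16 alternatives, and was lost, among others, without the arrays labelled mre11delta (adjusted p = 0.515), without wild type (adjusted p = 0.322), within the RNeasy pairs (adjusted p = 0.429), with median centring (adjusted p = 0.0651) and with quantile normalization (adjusted p = 0.0961). Of 32 proteasome genes 0 passed the test and 0 passed adjusted over the list alone. The camera call of the proteasome list as higher (relative median 0.28, adjusted p = 0.0479, and adjusted p = 0.862 with an estimated correlation) was kept in 9 of 16 alternatives, and was lost without wild type (adjusted p = 0.174), without the arrays labelled mre11delta (adjusted p = 0.282), without rad50delta (adjusted p = 0.111), without shared probe sets (adjusted p = 0.0598), with the floor of 70 (adjusted p = 0.0882), with extraction method as a covariate (adjusted p = 0.180) and within the RNeasy pairs (adjusted p = 0.856). Of the telomere-proximal families 2 of 10 rose, and 8 adjusted over the list alone, but 5 of the 10 have only a shared probe set and are uncertain. The camera call of the telomere-proximal list (adjusted p = 0.00478, and adjusted p = 0.663 with an estimated correlation) was lost without those 5 (adjusted p = 0.0586), without the arrays labelled mre11delta (adjusted p = 0.0563) and within the RNeasy pairs (adjusted p = 0.292), and 0 of its genes rose without wild type.

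The other 10 lists were not called by camera, and the other scalings moved their counts of rises and falls by at most 2 genes. Other settings moved some of them further, with 8 phosphate and 6 stress genes rising without spo11Y135F, and 8 stress genes falling and 6 TCA genes rising within the RNeasy pairs. Of the phosphate regulon 3 of 16 rose, and 4 adjusted over the list alone (adjusted p = 0.0901), with the phosphatase PHM8 (YER037W) at 2.51 ± 0.55, and the list was called as higher without rad50delta (adjusted p = 0.0192) and without spo11Y135F (adjusted p = 0.00199). Of the iron regulon 1 of 17 rose and 1 fell, and as many adjusted over the list alone (adjusted p = 0.128), and the list was called as lower without wild type (adjusted p = 0.0170) and with extraction method as a covariate (adjusted p = 0.0166). Among silent information regulators and telomere maintenance genes 4 of 17 rose, and 5 adjusted over the list alone (adjusted p = 0.157), with RIF1 (YBR275C) at 2.99 ± 0.63 and the telomerase subunit EST2 (YLR318W) at 2.56 ± 0.52. Of 12 auxotrophic and strain markers 2 fell, and 2 adjusted over the list alone (adjusted p = 0.182). Of the G1 cyclins and START genes 1 of 11 rose and 1 fell, and as many adjusted over the list alone (adjusted p = 0.431), with the START inhibitor WHI5 (YOR083W) at 2.68 ± 0.52. Among 18 genes of the DNA damage response 2 rose and 1 fell, and as many adjusted over the list alone (adjusted p = 0.482), with the stress protein DDR48 (YMR173W) at -2.10 ± 0.52. In the gluconeogenesis, glyoxylate and acetate list 2 of 19 rose and 3 fell, and as many adjusted over the list alone (adjusted p = 0.436), with the gluconeogenic enzyme FBP1 (YLR377C) at -2.17 ± 0.43 beside ALD6. Of 44 genes of the TCA cycle and respiration 0 passed, and 0 adjusted over the list alone (adjusted p = 0.482). Of the general stress list 3 of 33 rose and 1 fell, and 2 rose adjusted over the list alone (adjusted p = 0.870, and called as lower within the RNeasy pairs at adjusted p = 0.0472), with the chaperone SSA3 (YBL075C) at 3.42 ± 0.58. Of the sulfur assimilation list 3 of 24 rose and 3 fell, and as many adjusted over the list alone (adjusted p = 0.898), with the activator MET28 (YIR017C) at 2.82 ± 0.54 and the cysteine synthesis enzyme CYS3 (YAL012W) at -4.09 ± 0.71.

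Signs differed between measures in 4 of these lists. The sulfur list had a median change of 0.47 and a mean of 0.19 and was ranked lower by camera, and the gluconeogenesis list had a median of 0.15 and a mean of -0.15. The stress list had a median of -0.08 and a mean of 0.20 and was ranked lower, and the TCA list had a median of 0.06 and a relative median of -0.13. In all, camera called 17 of 27 lists, 12 higher and 5 lower, and 0 with an estimated correlation. The self-contained test fry called 4 of 27, which were the axis, break formation, strand exchange and entry lists.

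**Figure D1:**
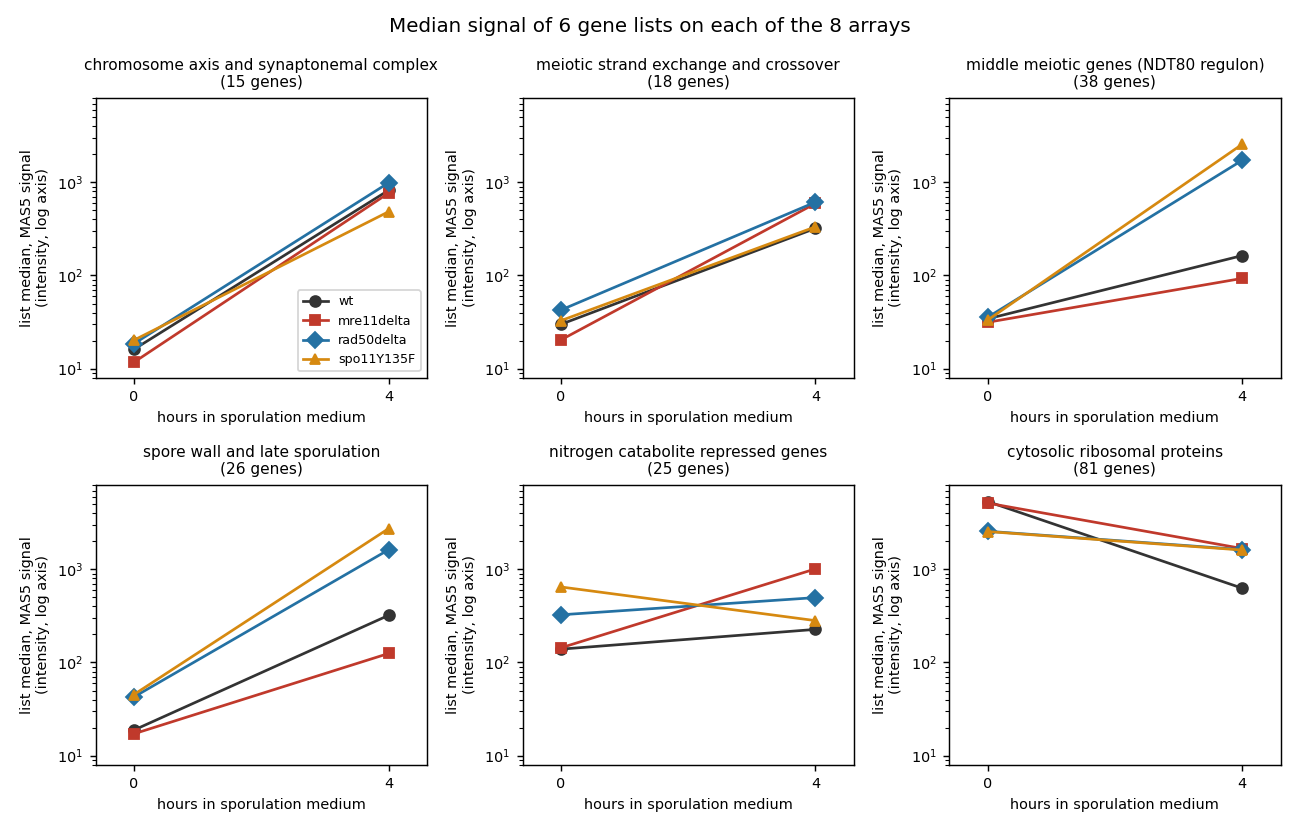
Median signal (linear intensity, log axis) of 6 gene lists at 0 h and 4 h, with 1 line per strain and 1 array per point. The axis list ends at 484 to 990 at 4 h, while the middle list ends at 93.1 in the arrays labelled mre11delta, 164 in wild type, 1727 in rad50delta and 2567 in spo11Y135F.

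At 4 h the strains differed most in middle meiotic and spore genes, which were lowest in the array labelled mre11delta and highest in spo11Y135F. The median signal of the middle list was 93.1 in the array labelled mre11delta, 164 in wild type, 1727 in rad50delta and 2567 in spo11Y135F. Signals of SPS4 (YOR313C), a middle sporulation gene, were 47.4 in the array labelled mre11delta, 1158 in wild type, 3735 in rad50delta and 3633 in spo11Y135F. Signals of SPR2 (YOR214C), a spore wall protein, were 2.9, 247, 5806 and 6941 in the same order. NDT80 (YHR124W), the activator of the middle genes, was chosen after its values were seen and had 4 h signals of 165 in the array labelled mre11delta, 226 in wild type, 936 in rad50delta and 1689 in spo11Y135F.

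In the array labelled mre11delta at 4 h, 17 of 38 middle genes and 13 of 26 spore genes stood apart below the other 3 strains, and 0 of either stood apart above. Relative to the median gene, the middle list lay at -3.77 against the mean of the other strains and the spore list at -4.16, both below all of the 10000 random lists. Without wild type these medians were -4.73 and -5.35, and without spo11Y135F the spore list lay at -3.32. The largest gaps below between signals above the floor were in RRT5 (YFR032C, -4.64), SPS4 (-4.42) and SPS2 (YDR522C, -3.73), where a gap is the log2 distance to the nearest other strain. SPR2 lies below the floor in this array, so its gap depends on the pseudocount. Above the other strains stood 24 of 49 amino acid biosynthesis genes and 15 of 25 nitrogen catabolite repressed genes, which became 10 and 6 with median centring. Examples were the ammonium permease MEP2 (YNL142W), at 4564 against 193 in the next strain, the allantoin pathway gene DAL3 (YIR032C), at 794 against 52.8, the amino acid permease GAP1 (YKR039W), at 4546 against 466, and the histidine enzyme HIS4 (YCL030C), at 3083 against 337. The relative median was 0.96 for the amino acid list, 1.01 for the nitrogen list and -1.18 for the phosphate regulon. Over all 5559 genes, 675 stood apart above and 78 below, and 150 and 199 with median centring, so that only 149 and 77 did so under all 3 scalings. This array is the only one at 4 h that was extracted with Trizol.

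In wild type at 4 h, 44 of 81 ribosomal protein genes stood apart below the other strains, with RPL37A (YLR185W) at a signal of 170.0 against 2301 to 2661 elsewhere, and so did 27 of 48 ribosome biogenesis genes, with the nucleolar protein NSR1 (YGR159C) at 64.0 against 829 to 1110 elsewhere. These counts were 7 and 6 with median centring, and the relative medians of the lists were -0.66 and -0.94. In the G2/M cluster 6 of 16 stood apart below, and 4 with median centring. Relative to the median gene the axis list lay above the other strains by 0.89, but 0 of its 15 genes stood apart above. As deposited its median signal was 822, against 767 in the array labelled mre11delta, 990 in rad50delta and 484 in spo11Y135F. The middle list lay below by a relative median of -1.23, a value that was -0.25 without spo11Y135F and -2.85 without the arrays labelled mre11delta. The spore list lay at -0.91, and at 0.13 without spo11Y135F, which turns its direction. Over all genes 4 stood apart above and 768 below, and 32 and 84 with median centring, with 4 and 84 under all 3 scalings. The 4 genes above were the glycolytic activator TYE7 (YOR344C), DDR48, the recombination gene RAD59 (YDL059C) and AUA1 (YFL010W-A). TYE7 read 31.3 against 3.4 in the next strain and AUA1 23.2 against 6.9, near or below the floor on both sides, so their gaps depend on the pseudocount.

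In spo11Y135F at 4 h the relative median against the other strains was 3.05 for the middle list and 3.14 for the spore list, above all of the random lists. Leaving out a strain moved these medians between 1.98 and 4.15 and between 1.87 and 4.11. Of 38 middle genes 5 stood apart above the other strains, and 13 with median centring. Below the other strains stood 11 of 29 S phase and replication genes, 7 of 15 axis genes and 4 of 10 break formation genes, and 6, 2 and 4 with median centring. Relative medians were -0.64 for S phase, -0.99 for the axis and -0.72 for break formation, and 1.19 for ribosome biogenesis. The largest gaps were in the hexose transporter HXT10 (YFL011W), at 868 against 106 in the next strain, and the transcription factor GAT4 (YIR013C), at 2802 against 414, and on the low side the TFIID subunit TAF12 (YDR145W) read 2.7, below the floor, against 139. Over all genes 231 stood apart above and 517 below, and 508 and 408 with median centring, with 226 and 327 under all 3 scalings.

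In rad50delta at 4 h few genes stood apart, 14 above and 5 below, and 2 and 21 with median centring, with 2 and 5 under all 3 scalings. Below stood RAD50, at 3.4 against 272 in the next strain, and, below the floor on both sides of the gap, SPT6 (YGR116W), a histone chaperone, at 2.6 against 15.3 and URA3 at 2.5 against 14.8. The largest gaps above were those of the glycerophosphoinositol transporter GIT1 (YCR098C, 1.99) and of NCA3 (YJL116C, 1.81). The middle and spore lists had relative medians of 1.93 and 1.99 against the other strains, and 0.71 and 0.54 without the arrays labelled mre11delta. Leaving out a strain moved the counts at 4 h from 19 genes to between 58 and 390 in rad50delta, from 772 to between 946 and 1321 in wild type, from 753 to between 830 and 1353 in the array labelled mre11delta and from 748 to between 822 and 1279 in spo11Y135F. The direction of these moves was set by the rule, since with fewer strains to compare gaps can only stay or grow.

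**Figure D2:**
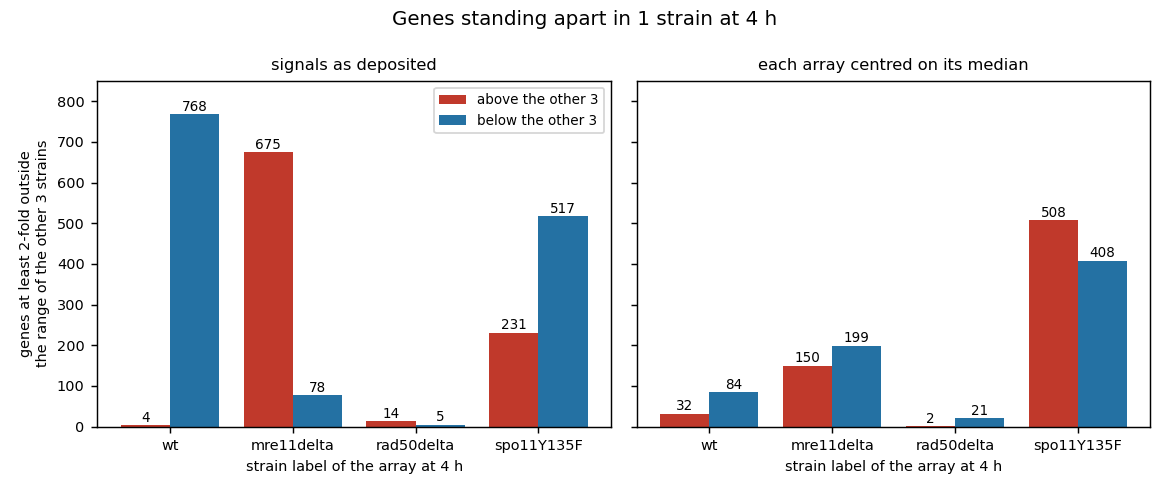
Number of genes (linear axis from 0) standing apart above (red bars) or below (blue bars) the other 3 strains at 4 h, by strain, as deposited and with median centring. As deposited, wild type has 768 genes below and the array labelled mre11delta 675 above, and with median centring these bars stand at 84 and 150 while spo11Y135F has 508 above and 408 below.

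Set against wild type alone at 4 h, the middle list had a relative median of -1.77 in the array labelled mre11delta, 2.22 in rad50delta and 3.19 in spo11Y135F. The spore list gave -1.90, 1.93 and 2.75 in the same order, each value outside all of the random lists. As deposited the medians were -0.83, 2.87 and 3.52 for the middle list and -0.96, 2.58 and 3.07 for the spore list. The axis list had relative medians of -0.84 in the array labelled mre11delta, -0.46 in rad50delta and -1.46 in spo11Y135F, but its medians as deposited were 0.09, 0.19 and -1.14, so that the sign turned with the scaling in all but spo11Y135F. In the G2/M cluster the relative median was 0.20 in the array labelled mre11delta, 1.39 in rad50delta and 1.72 in spo11Y135F, and as deposited 1.13, 2.04 and 2.04. The phosphate regulon lay at -1.39 in the array labelled mre11delta (-0.45 as deposited), and the nitrogen list at 0.75 in the array labelled mre11delta (1.69) and -0.86 in spo11Y135F (-0.54). All 3 comparisons share the wild-type array, and only the array labelled mre11delta also differs from it in extraction method.

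At 0 h the arrays formed pairs that share an extraction method, wild type with the array labelled mre11delta (Trizol) and rad50delta with spo11Y135F (RNeasy). Relative to the median gene, 134 genes were at least 2-fold apart within the Trizol pair and 274 within the RNeasy pair, while 1559 were so between wild type and rad50delta. IME1 (YJR094C), the master activator of meiosis, chosen after its values were seen, had signals of 699 in wild type and 514 in the array labelled mre11delta against 4896 in rad50delta and 5576 in spo11Y135F. The phosphate regulon had relative medians of -1.25 in wild type, -1.72 in the array labelled mre11delta, 1.27 in rad50delta and 1.65 in spo11Y135F. General stress genes lay at -0.40, -1.13, 1.02 and 0.56, and ribosomal protein genes at 0.55, 0.62, -0.40 and -0.77, in the same order.

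Few genes stood apart in a single strain at 0 h. The counts above and below were 12 and 25 in wild type, 2 and 79 in the array labelled mre11delta, 10 and 124 in rad50delta and 185 and 32 in spo11Y135F, of 5474 genes. With median centring they were 36 and 37 in rad50delta and 27 and 85 in spo11Y135F. In rad50delta URA3, at 4.4 against 357 in the next strain, and RAD50, at 0.6 against 88.4, stood below, and the chaperone SSA3 (2.02) had the largest gap above. In the array labelled mre11delta the cell wall protein PIR3 (YKL163W), at 19.3 against 173 in the next strain, stood below, and in spo11Y135F the cohesin factor PDS5 (YMR076C), at 2.1 against 58.3. In wild type the stationary phase gene SPG4 (YMR107W) read 116 against 557 in the next strain. Without the other strain of the same extraction method the counts were 1169 genes in wild type, 1283 in the array labelled mre11delta, 1407 in rad50delta and 1549 in spo11Y135F. By the rule such counts can hardly fall, so only the size of the rise describes the arrays.

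Within strains, the change from 0 h to 4 h differed most in the same meiotic lists. The middle list had a relative median change of 2.43 in wild type, 0.82 in the arrays labelled mre11delta, 4.52 in rad50delta and 5.77 in spo11Y135F, and the spore list 3.09, 1.42, 4.45 and 5.81. For the axis list the values lay closer together, at 5.81, 5.12, 4.73 and 4.29. For the nitrogen list the values were 0.81, 2.02, -0.03 and -0.76, and for the phosphate regulon 1.90, 0.97, -0.08 and -0.98. The change stood apart above the other strains in 930 genes for the arrays labelled mre11delta, 237 for rad50delta, 197 for spo11Y135F and 17 for wild type, and below in 58, 11, 1013 and 1066. With median centring the counts above were 225, 41, 668 and 176 and those below 208, 96, 507 and 126. As examples, MEP2 went from 20.8 to 4564 in the arrays labelled mre11delta, and the ribosomal protein gene RPL22B (YFL034C-A) from 816 to 6.8 in wild type. Extraction method was constant within each mutant and changed between the times in wild type. Without a strain the totals moved from 1083 to between 1165 and 2029 in wild type, from 988 to between 1061 and 1989 in the arrays labelled mre11delta, from 248 to between 290 and 1381 in rad50delta and from 1210 to between 1256 and 2165 in spo11Y135F. Here, too, the rule sets the direction of the moves.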

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

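Of the tests in this part, only the count over other groupings of the arrays and the test of the extraction method on the 0 h genes were planned before their results were seen, and every other test was chosen only after.

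The middle and spore genes lay lower in the array labelled mre11delta than in any other strain at 4 h. A scaling factor for the whole array does not account for it, since it would move all genes alike, while relative to the median gene of the array the middle list lay at -3.77 and the spore list at -4.16 against the other strains. The extraction method could not be told apart from the strain, because this is the only Trizol array at 4 h, and the middle list already spans 3.92 in log2 over the 3 arrays of the other method. A culture less advanced than wild type could not be decided either, since the axis list, whose genes act earlier, differed from wild type by 0.0926 as deposited and by -0.84 relative to the median gene. A biological difference between the strains may remain, and a second culture of each strain extracted with a single method would tell.

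URA3 read 496 in the array labelled wild type at 0 h and 14.8 in that labelled wild type at 4 h. A fall over time of like size in all strains did not account for it. The fall in wild type exceeded the larger of the other falls by 2.64 in log2 on the probe set where the excess was smaller. However, URA3 was lower at 4 h in all 4 strains, with a fitted change of -1.87 (limma adjusted p = 0.0408). That fit includes the wild-type fall itself, and its call was lost in 7 of 16 alternatives, among them without wild type. In rad50delta both readings, 4.4 at 0 h and 2.5 at 4 h, lay below the pseudocount of 7, so its fall carries no weight. In wild type 1066 genes had a change at least 2-fold below that of every other strain as deposited, but only 126 with median centring. A shared fall that was deeper in wild type therefore stays open. A total loss of the URA3 signal in every array of glass beads and RNeasy was excluded, since spo11Y135F, of that method, read 357 at 0 h. A partial loss, or a loss at 4 h only, was not tested and stays open. At 4 h wild type, rad50delta and spo11Y135F, all of that method, read 14.8, 2.5 and 91.3, and the Trizol array 273. A sample of another strain under the label of wild type at 0 h could not be excluded either. Only 134 genes were at least 2-fold apart between that array and the array labelled mre11delta at 0 h, against 274 between rad50delta and spo11Y135F. How many genes 2 arrays of a single strain would show is not known here, so these counts do not decide. Sequence-level genotyping of the RNA could decide it.

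At 0 h the mean of rad50delta and spo11Y135F (RNeasy) lay at least 2-fold from wild type (Trizol) in 1609 genes, by a median of 1.49 in log2. These arrays differ in strain and culture as well as in extraction method. If the method acted alike at 4 h, the same genes should differ between wild type (RNeasy) and the array labelled mre11delta (Trizol), but their signed median difference was 0.0537, with 52.5% of genes on the same side. With the array labelled mre11delta in place of wild type at 0 h, the value was 0.0587 over 1741 genes. The 0 h differences thus did not recur as a set between these arrays at 4 h. Method went with strain in both comparisons, so the values do not separate an effect of the method from the strains. An effect of the method confined to 0 h was not tested and stays open, as do the strains and their cultures.

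The time effect was compared with the other ways to divide the 8 arrays into 4 and 4 that the model can fit. Only 1 of 32 groupings, that by time, called as many as 802 genes, and the highest of the others called 137, while 3 more groupings could not be fitted. The groupings that called 137 set 0 h against 4 h in rad50delta and spo11Y135F alone. They thus hold the time effect of these strains, and 1 of 32 is not a level of chance. Of the 32 groupings, only 8 part the 2 arrays of every strain, as that by time does. The highest other count among these 8 was 0. With 8 such groupings the share cannot fall below 1 of 8, so this comparison alone cannot exclude chance.

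In 7 of 93 named genes and 0 of 27 lists, the change in a single strain lay outside that in the other 3 strains by Dixon's ratio at its 5% level for 4 values. About 4.65 of 93 genes would pass at that level by chance. All of the 7 but RPS22A and SIR1 had a signal below the floor of 21 in at least 1 strain, where the pseudocount sets part of the value. CHS2 changed by -4.46 in wild type and by -1.54 to -1.26 in the others. DAL80 changed by 5.77 in the arrays labelled mre11delta and by 2.71 to 2.95 in the others. HOP2 changed by 4.21 in spo11Y135F and by 5.65 to 5.91 in the others. LDS2 changed by 4.22 in the arrays labelled mre11delta and by 7.04 to 7.47 in the others. RPS22A changed by -4.97 in wild type and by -2.32 to -1.96 in the others. SIR1 changed by 1.59 in wild type and by 2.51 to 2.64 in the others. SPO13 changed by 4.24 in spo11Y135F and by 6.42 to 6.75 in the others.

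In 22 of 81 comparisons of a list between a mutant and wild type, the relative median change had the opposite sign. In 3 of these both values lay outside the central range of random lists, and the differences were not tested. For ribosome biogenesis it was 0.54 in spo11Y135F and -1.91 in wild type. For nitrogen catabolite repressed genes it was -0.76 in spo11Y135F and 0.81 in wild type. For the phosphate regulon it was -0.98 in spo11Y135F and 1.90 in wild type.

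Signals outside the gene analysis changed as well. Of 1279 probe sets with no gene name that could be tested, 114 passed the threshold from 0 h to 4 h in limma, 88 higher and 26 lower. Of 280 probe sets with several genes, 43 passed, 16 higher and 27 lower. Among the tested genes, the 25S rRNA gene RDN25-1 (YNCL0012C) changed by -4.07 ± 0.50 (limma adjusted p = 6.24e-06). The 25S rRNA controls were not tested, and 4 of their 5 probe sets read lower at 4 h in every strain. The probe set with the highest signals at 0 h had a ratio of 0 h to 4 h signal of 5.13 in the arrays labelled mre11delta, 15.0 in wild type, 16.9 in rad50delta and 25.6 in spo11Y135F. The remaining probe set read higher at 4 h in 3 strains and lower in rad50delta. Polyadenylated RNA was selected before labelling, so rRNA signals can depend on that selection as well as on the cells. An 18S rRNA control, for example, read 5010.6 in wild type and 923.3 in the array labelled mre11delta at 0 h, both extracted with Trizol. A fall of rRNA in the cells therefore does not follow from these values.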

How the results depend on the processing

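Among the alternatives, only the fit within the RNeasy pairs was chosen after seeing the data. The direction of the change from 0 h to 4 h over the strains held under every alternative for the meiotic lists and the ribosomal protein list, and 54 of 93 genes named for the time effect kept their call in all settings. Of 17 called lists 9 kept their call in all 16 alternatives run with camera's preset correlation. Counts are given below where they moved by over 1.5 times, and list medians where they moved by over the SD of random lists or turned their sign. The cause was not tested, except that leaving out a strain removes arrays from both sides and that the within-method comparisons at 4 h and of the change equal leaving out mre11delta and wild type. Weak signals limit small values, since 5 values were 0 and the pseudocount of 7 shrinks changes near it.

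Median centring gave 560 genes lower, and genes standing apart numbered 73 (rad50delta) and 112 (spo11Y135F) at 0 h, 116 (wild type) and 349 (mre11delta) at 4 h, and 302 (wild type), 433 (mre11delta) and 137 (rad50delta) for the change. Quantile normalization gave 378 genes lower, 50 (mre11delta) and 99 (spo11Y135F) at 0 h, 157 (wild type) and 338 (mre11delta) at 4 h, and 328, 416 and 120 for the change in wild type, mre11delta and rad50delta. With it, rad50delta lay at 2.14 (middle) and 2.24 (spore) against the others and at 2.36 and 2.11 against wild type, and the TCA list changed by -0.0049 in spo11Y135F against the others, a reversed sign. Extraction as a covariate called 382 genes, 346 higher and 36 lower, a setting that rests on the mutants alone, as leaving out wild type does. Within the RNeasy pairs, a fit with fewer residual degrees of freedom than the main fit, 1214 genes and 10 lists were called, 355 genes lower. There PHO89 turned to -0.27, and the lists of ribosome biogenesis (0.34), nitrogen (0.23) and proteasome (0.022) changed the direction ranked by camera and lost their call, and 5 more lists lost theirs. Without the strain block 820 genes changed, a count that did not move as far. With camera's estimated correlation 0 lists were called, and with fry 4, and 8 at unadjusted p by fry.

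A pseudocount of 1 gave 59 (wild type) and 126 (mre11delta) genes at 0 h. A pseudocount of 28 gave 10, 26, 65 and 139 in wild type, mre11delta, rad50delta and spo11Y135F at 0 h, and 9 at 4 h and 164 for the change in rad50delta. With it the middle list lay at -3.46 in mre11delta and 2.79 in spo11Y135F against the others and at -1.56 and 2.87 against wild type, and the spore list at -3.81 and -1.65 in mre11delta. The mean of all probe sets moved the spore list to 1.88 in rad50delta and to -1.72 in mre11delta against wild type. Without shared probe sets the telomere-proximal list turned to 0.022 in mre11delta against wild type at 0 h. The floor of 70 left 12 genes in rad50delta at 4 h. A 3-fold rule left 188, 191, 6 and 171 genes at 4 h in wild type, mre11delta, rad50delta and spo11Y135F. Within an extraction method at 0 h, 145 genes were apart between wild type and mre11delta, and 522 between rad50delta and spo11Y135F. With only a pair of arrays the rule gives the same count for both.

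With a strain left out, 364 to 888 genes changed, 328 to 637 higher and 36 to 264 lower, with 12 to 18 lists called. Counts of genes standing apart can by the rule hardly fall with a strain left out, so their rise is no check. Genes standing apart at 0 h were 38 to 1169 in wild type, 92 to 1283 in mre11delta, 148 to 1407 in rad50delta and 246 to 1549 in spo11Y135F. At 4 h they were 946 to 1321, 830 to 1353, 58 to 390 and 822 to 1279 in that order, and for the change 1165 to 2029, 1061 to 1989, 290 to 1381 and 1256 to 2165. The middle list at 4 h ran from -2.85 to -0.25 in wild type, -4.73 to -3.004 in mre11delta, 0.71 to 3.32 in rad50delta and 1.98 to 4.15 in spo11Y135F. The spore list ran from -2.31 to 0.13, -5.35 to -3.32, 0.54 to 3.32 and 1.87 to 4.11. Signs reversed for the spore list in wild type (0.13 without spo11Y135F). In rad50delta at 4 h they reversed for ribosome biogenesis (-0.0037 to 0.84) and ribosomal proteins (-0.12 to 0.36), lowest without wild type, and for nitrogen (-0.69 to 0.022), highest without mre11delta. For the change they reversed in rad50delta for the axis (-0.82 to 0.069, highest without wild type) and spore lists (-0.34 to 2.31, lowest without mre11delta), and in wild type for the middle (-2.60 to 0.097) and spore lists (-1.87 to 0.62), highest without spo11Y135F.

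Among named genes over time 1304 of 1484 values kept their call, 179 lost it and 1 reversed. For the called lists over time 243 of 306 values kept their call, 60 lost it and 3 reversed, and 5 of 180 values of the other lists gained one. Of 1068 gaps of named genes 71 moved.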

Other observations

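The tests behind this part were all chosen before their results were seen, apart from the choice to report these RNA classes, which came after.

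Small RNAs that lack a polyadenylated tail were compared without a test, and their signals can depend on the selection of polyadenylated RNA as well as on the cells. The median signal of 91 tRNA genes was 50.0 in wild type, 41.3 in the array labelled mre11delta, 94.0 in rad50delta and 130.4 in spo11Y135F at 0 h, and 16.8, 59.0, 26.9 and 37.6 at 4 h. For 57 snoRNA genes, guides of ribosomal RNA modification, the medians were 54.0, 49.0, 63.7 and 71.0 at 0 h and 20.2, 39.2, 39.5 and 43.2 at 4 h. SNR6 (YNCL0006W), the U6 spliceosomal RNA, had a log2 change of -3.39 ± 0.57 (SE, n = 4 strains, limma adjusted p = 0.000233). OLI1 (Q0130), a mitochondrially encoded subunit of the ATP synthase, was named after its values were seen and had a log2 change of -0.36 ± 0.38, which did not pass the test (adjusted p = 0.575).

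The signal ratio between the 3' and 5' ends of control transcripts, a sign of RNA integrity, ran from 1.43 to 1.72 for ACT1, from 2.00 to 3.92 for SPT15 and from 1.68 to 3.804 for SRB4 over the 8 arrays. LEU2, a leucine synthesis gene used as a strain marker, read differently on its 3 probe sets. On a shared set it had signals of 20.7 and 2.5 in wild type, 3.0 and 9.8 in the arrays labelled mre11delta, 817.7 and 844.6 in rad50delta and 2305 and 302 in spo11Y135F, at 0 h and 4 h, which parts the strains into the same pairs as the 0 h arrays. On the set with the highest signals these were 1112 and 3855, 792.5 and 6123, 1659 and 1909, and 3404 and 549, in the same order, and at 4 h the order of the pairs was turned.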
